A study of Mus musculus with 18 samples.

How the data were processed

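Transcript levels were measured on 18 Affymetrix arrays, each hybridised with RNA from Brunner's glands of 1 male CD-1 mouse. Brunner's glands are mucus-secreting glands in the submucosa of the duodenum, and laser capture microdissection cuts them out of a tissue section under the microscope. The design text of the series states that the arrays came from individual mice, so each array is 1 animal and no array was counted more than once. The labels place the arrays in 6 groups of 3: wild-type and GLP-1R-/- mice, each untreated, 6 h after exendin-4 or 18 h after exendin-4. Exendin-4 is a peptide agonist of the receptor for glucagon-like peptide 1, the receptor missing in the GLP-1R-/- mice.

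Per the labels, total RNA was isolated with TRIzol, cleaned on RNeasy MinElute columns, checked on a Bioanalyzer and labelled with biotin through Affymetrix in vitro transcription. The deposited values are log2 signals that the authors made with RMA, per the submitters' processing notes, which give no version. RMA corrects the background of each array, normalises the arrays to one another and summarises the probes of a set. It gives no detection call, so a dim gene cannot be told from an absent one, and its background step compresses the fold changes of dim genes. The array model, the probe set definition and the genome build are not given in the sources used here. Array medians lay between 5.88 and 6.11 on the log2 scale and single values between 2.89 and 14.8. For arrays no read depth exists, and the number of arrays limits the precision.

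The table had 17204 rows, each headed by 1 Ensembl mouse gene identifier, so no choice between probe sets of a gene was needed. Neither the table nor the reference gene table (assembly GRCm38.p6) paired these identifiers with symbols: 0 of the reference rows carried an Ensembl identifier. Genes are therefore given by identifier, without names, functions or coordinates. The 31 gene lists chosen by symbol, the genes chosen by symbol, the level of the receptor transcript as a check of the genotype labels and the markers of other cell types were not analysed here. The 3' to 5' control ratios of RNA quality were not analysed here either.

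Genes were tested if at least 3 of the 18 arrays lay above 4.79, the 30th percentile of all values, which left 12775 genes. A linear model with 1 mean per group was fitted to the log2 values of all 18 arrays with limma 3.58.1 in R 4.3.3, followed by eBayes, and p-values were two-sided with Benjamini-Hochberg adjustment over the 12775 genes. A gene was called at an adjusted p under 0.05. The contrasts were each treated group against the untreated group of its genotype, 18 h against 6 h in each genotype, GLP-1R-/- against wild-type untreated mice, and the genotype by treatment interaction at each time. The design, the contrasts and all alternatives not marked as later were chosen before the data were examined. The genotype by time contrast, which subtracts the 18 h against 6 h difference of the knockout from that of the wild type, is not part of that design: it was added after the data had been examined, before its own result was computed. The labels number each array once across the whole series and give no batch, so nothing pairs or blocks the arrays.

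The rule for naming genes took those with the largest rise and the largest fall among the called genes whose 3 treated arrays all lay on one side of the 3 untreated ones, separately for wild-type mice at 6 h and at 18 h. It was set to take 12 genes in each direction, and 5 for the other contrasts. Because no identifier has a name here, it was reduced to the first place in each direction and the 2 wild-type contrasts against untreated mice. One identifier held both the largest rise at 6 h and the largest fall at 18 h, so 3 identifiers are printed.

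For sets of called genes a score was computed per array: the mean over the set of the difference from the wild-type untreated mean, with the sign turned to the direction of the call. Because a score is inflated in the arrays that selected its genes, the wild-type change was also measured in held-out arrays: genes were called without 1 treated and 1 untreated array, and scored in those, for all 9 such pairs. Each pair has its own list, shorter than the full one, and the knockout change was computed over the same lists. It used the same knockout group means for every list, so its range varies with the lists alone. Scores were compared with exact two-sided permutation tests, whose smallest possible p with 3 against 3 arrays is 0.1. The 6 h and 18 h contrasts share their untreated arrays, so 100 simulated pairs of unchanged groups against shared controls were drawn. They give a chance value of the correlation of the changes. They give none for the overlap of the real lists, since no gene was changed in them. In a check chosen after the data were seen, the 3 untreated wild-type arrays were also split 2 and 1 between contrasts that share them, in all 6 ways; the lone array was assumed to vary like the other groups.

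The procedure was tested on simulated data for 12775 genes, of which 200 were changed by known amounts, in 20 simulations. In the simulated wild-type 6 h contrast it recovered 18.6% of changes of 0.5, 85.1% of changes of 1 and 99.0% of changes of 2 on the log2 scale, and 4.06% of its calls were false. In the simulated genotype by treatment contrast at 6 h it recovered 3.21%, 47.1% and 95.4% of the same sizes, and 5.11% of its calls were false. A simulated knockout 6 h contrast with no change gave 0 calls with limma. These shares hold for the simulated noise only. The real arrays were unequal, with limma's array weights from 0.084 for knockout 6 h replicate 13 to 2.84 for knockout 6 h replicate 14. Whether the shares of recovered changes and false calls hold for such arrays was not tested.

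The alternatives were no filter, a filter at the 50th percentile, quantile normalisation, centring each array on its median, limma's array weights, eBayes with trend and robust, a fit to only the groups in the contrast, a threshold of 0.1, an added minimum change of 1 on the log2 scale, and leaving out each array in turn. A further alternative, chosen after the data were seen, left array 13 out of the shared spread in contrasts that do not use its group. Every count of calls was also set against other splits of the same arrays into groups of the same sizes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.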

Results

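Gene expression was profiled in laser-captured Brunner's glands of male CD-1 mice to compare the response to exendin-4 with and without its receptor. Each of the 6 groups held 3 mice: wild-type and GLP-1R-/- animals, untreated or collected 6 h or 18 h after exendin-4. Of 17204 genes on the arrays, 12775 were bright enough to be tested. Pairs of arrays correlated across genes between 0.970 and 0.995, except those with knockout 6 h replicate 13, which correlated between 0.945 and 0.966 with the others. The first principal component held 25.1% of the variance and set replicate 13 apart from the other 17 arrays. The second held 17.9%. Values are RMA signals on the log2 scale, and adjusted p-values are from limma over the 12775 genes. The genes are given as Ensembl identifiers because the files do not pair them with symbols.

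Wild-type mice were compared 6 h after exendin-4 and untreated to find which transcripts differed early after the agonist. The labels give only untreated mice as controls and name no vehicle-injected or time-matched group. Within a genotype, injection and time of collection therefore cannot be told apart from the agonist. The largest rise belonged to ENSMUSG00000024810, whose level went from 8.73 ± 0.521 (SD, n = 3) to 12.6 ± 0.277 (SD, n = 3). This was a 14.6-fold rise, or 3.87 on the log2 scale (SE 0.252, limma adjusted p = 3.42e-07). ENSMUSG00000070645 rose 5.72-fold, by 2.52 on the log2 scale (SE 0.387, limma adjusted p = 0.00146), from a level of 5.09, near the filter level of 4.79. The largest fall belonged to ENSMUSG00000033826, which fell by 2.19 on the log2 scale (SE 0.351, limma adjusted p = 0.00186), from 10.2 ± 0.773 to 7.99 ± 0.793 (SD, n = 3 each). For each of these 3 genes, all 3 treated arrays lay on one side of all 3 untreated arrays. The naming rule required this of the largest rise and the largest fall.

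In all, 433 genes were called at 6 h in wild-type mice, of which 247 rose and 186 fell. The rises had a median of 0.77 on the log2 scale, or 1.71-fold: 13 genes rose at least 4-fold, 53 between 2-fold and 4-fold, and 181 less than 2-fold. The falls had a median of -0.81, or 1.75-fold lower: 2 genes fell at least 4-fold, 37 between 2-fold and 4-fold and 147 by less. Among the genes that rose, 11 started below the filter level of 4.79, and 11 of those that fell ended below it. The untreated level lay among the brightest 10% of tested genes for 10.1% of the genes that rose and 17.7% of those that fell. At an unadjusted p under 0.05 there were 1843 genes, where chance gives 638.8, and 23.8% of tested genes had groups that did not overlap, where chance gives 10%. The count was 181 without untreated replicate 1, 226 without untreated replicate 2, 206 without 6 h replicate 7 and 176 without 6 h replicate 9. It was 1243 with limma's array weights, which gave replicate 13 a weight of 0.084, and 880 when that array was left out of the shared spread.

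**Figure D1:**
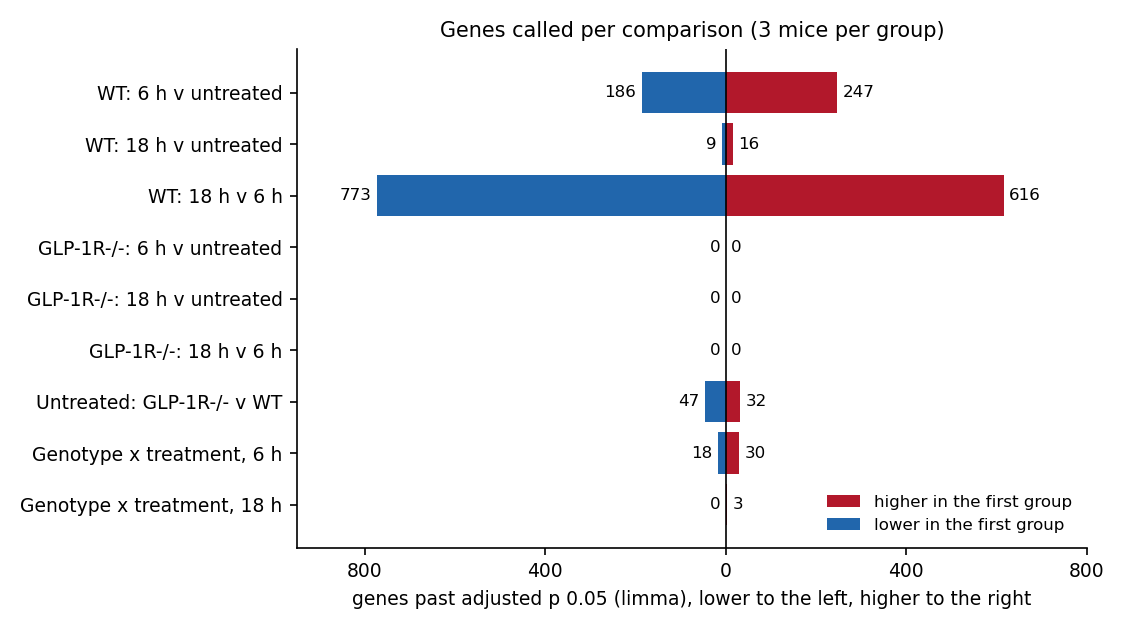
Number of genes past an adjusted p of 0.05 (limma, 3 mice per group) in each comparison, with genes lower in the first-named group as bars to the left and higher ones to the right. For the genotype by treatment contrasts, right means a more positive change in wild-type mice. Wild-type mice had 433 calls at 6 h and 1389 between 18 h and 6 h, and the 3 contrasts within the GLP-1R-/- mice had 0.

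At 18 h the same comparison in wild-type mice called 25 genes, 16 higher and 9 lower. ENSMUSG00000070645 had the largest rise, 26.5-fold or 4.73 on the log2 scale (SE 0.387, limma adjusted p = 1.22e-05), to a level of 9.82 ± 0.773 (SD, n = 3). ENSMUSG00000024810, the gene with the largest rise at 6 h, had the largest fall at 18 h: its level of 7.18 ± 0.198 (SD, n = 3) was below that of untreated mice by -1.55 on the log2 scale (SE 0.252, limma adjusted p = 0.016, between 0.00444 and 0.117 over 14 alternatives). That call was lost without untreated replicate 1 (adjusted p = 0.0648), 18 h replicate 10 (0.0638), replicate 11 (0.0542) or replicate 12 (0.0563), and in a limma fit to only the groups compared (adjusted p = 0.117). The differences were then -1.25, -1.44, -1.63, -1.59 and -1.55, in the same order. ENSMUSG00000033826 was at 9.79 ± 0.174 (SD, n = 3), a difference of -0.39 from untreated mice (SE 0.351, limma adjusted p = 0.834).

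The 16 rises at 18 h had a median of 1.06 on the log2 scale and the 9 falls a median of -0.90. At an unadjusted p under 0.05 there were 1073 genes against 638.8 by chance, and 16.4% of tested genes had groups that did not overlap, where chance gives 10%. That share does not set wild-type mice apart, since it was 16.5% in knockouts at 18 h, where 0 genes were called. The count fell to 8 without untreated replicate 1, 11 without untreated replicate 2, 16 without 18 h replicate 10, 8 without replicate 11 and 8 without replicate 12. It was 4 in a fit to only the groups compared, 212 with array weights and 86 when array 13 was left out of the shared spread.

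**Figure D2:**
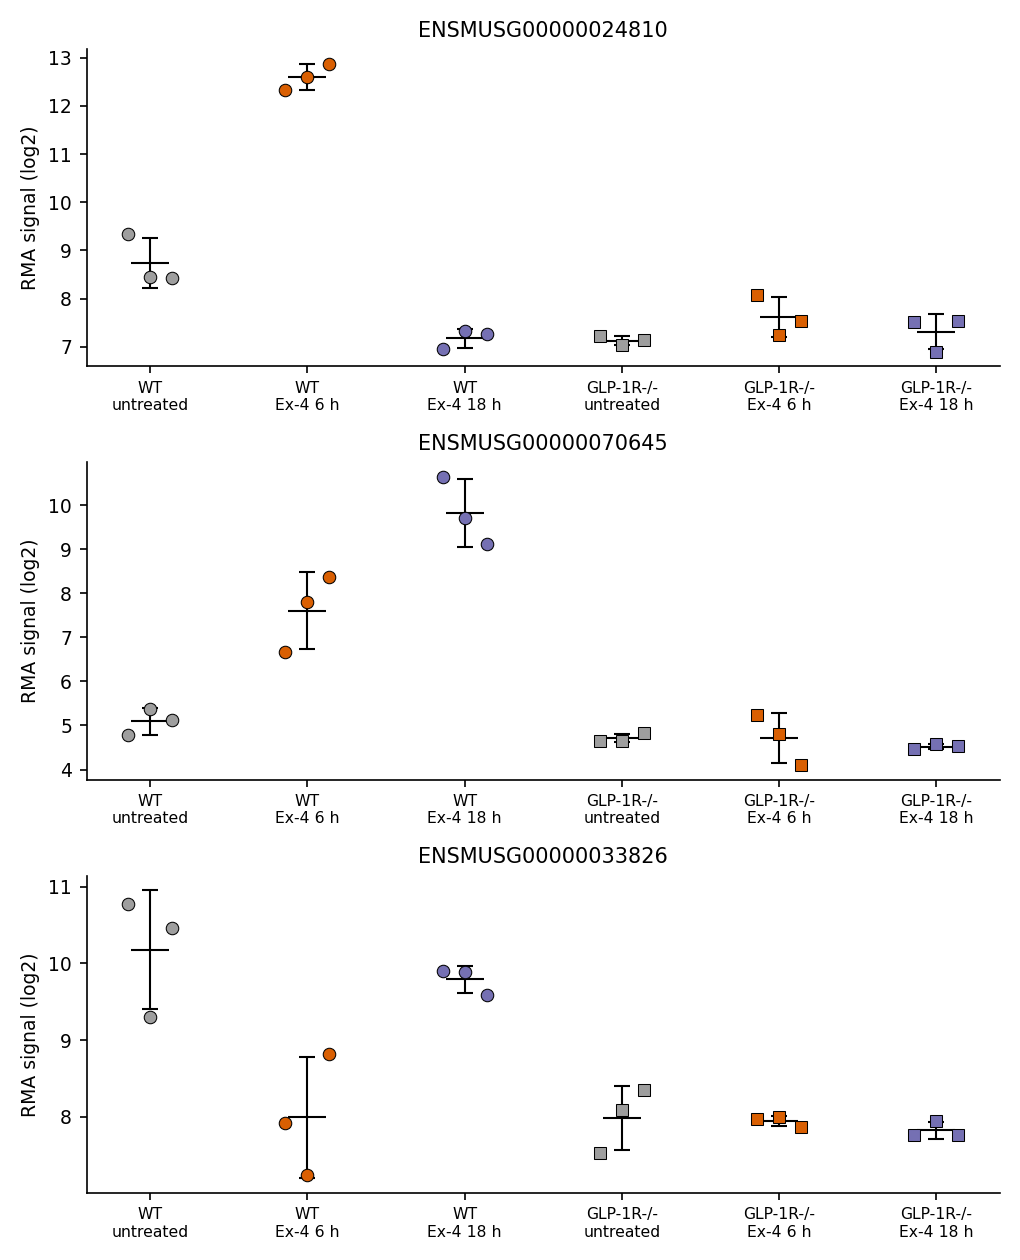
RMA signal on the log2 scale of the 3 named genes in each array, by group (circles wild-type, squares GLP-1R-/-; horizontal line and error bar, mean and SD of 3 mice). ENSMUSG00000024810 averaged 12.6 in wild-type mice at 6 h and between 7.13 and 8.73 in the other groups, ENSMUSG00000070645 averaged 9.82 in wild-type mice at 18 h and at most 4.71 in GLP-1R-/- mice, and ENSMUSG00000033826 averaged between 7.83 and 7.99 in the GLP-1R-/- groups.

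Of the 25 genes called at 18 h, 17 were not called at 6 h. Called at both times in the same direction were 5 genes: 4 that rose, where independent lists would share 0.309, and 1 that fell, where they would share 0.131. ENSMUSG00000070645 was 1 of the 4. Another 3 genes, ENSMUSG00000024810 among them, were called in opposite directions, where independent lists would share 0.407. Simulated unchanged groups that shared the controls had an average overlap of 0. As no gene was changed in them, there were few calls to share, so this gives no chance overlap for the real lists. Part of any sharing may come from the shared untreated arrays. With those arrays split 2 and 1 between the contrasts, in 6 ways, 1 to 2 genes were shared in the same direction, where independent lists would share 0.0194 to 0.185, and 0 to 3 in opposite directions (limma, with 4 to 17 calls at 18 h). Across genes, which are not independent replicates, the 6 h and 18 h changes had a Pearson r of -0.00216 and a covariance of -0.000166. The simulated unchanged groups had 0.501 and 0.0201, a difference in covariance of -0.0203. With the untreated arrays split, r lay between -0.299 and -0.106 and the covariance averaged -0.0197. The overlap of 5 was 2 without untreated replicate 1, 3 without untreated replicate 2, 2 without 6 h replicate 9, 3 without 18 h replicate 11 and 2 without 18 h replicate 12. It was 23 with array weights and 12 when array 13 was left out of the shared spread.

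Wild-type mice at 18 h were also compared directly with those at 6 h. ENSMUSG00000024810 was lower at 18 h by -5.43 on the log2 scale (SE 0.252, limma adjusted p = 1.58e-09). ENSMUSG00000033826 was higher at 18 h by 1.80 (SE 0.351, limma adjusted p = 0.00305), and ENSMUSG00000070645 was higher still than at 6 h, by 2.21 (SE 0.387, limma adjusted p = 0.00142). In all, 1389 genes differed, 616 higher and 773 lower at 18 h; with each array centred on its median the split was 474 higher and 939 lower. Of the 433 genes called at 6 h, 369 (85.2%) were called here in the opposite direction: 213 that had risen were lower at 18 h than at 6 h, and 156 that had fallen were higher. A single gene of the 433 was called here in its 6 h direction. Both contrasts use the 3 wild-type 6 h arrays that selected the 433 genes, which favours the opposite direction here. For the 9 lists of 81 to 319 genes called without 1 of the 6 h and 1 of the untreated arrays, the 18 h mean minus the held-out 6 h array averaged -1.04 in the direction of the call (between -1.26 and -0.80). Among the 1389 genes, 1005 (72.4%) were called at neither time against untreated mice. Groups did not overlap for 35.7% of tested genes, where chance gives 10%. The count was 842 without 18 h replicate 10, 874 without 6 h replicate 7 and 810 without 6 h replicate 9, 3423 with array weights and 2419 when array 13 was left out of the shared spread.

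Exendin-4 was also given to GLP-1R-/- mice, where a change would not need that receptor. ENSMUSG00000024810 had a level of 7.13 ± 0.0964 in untreated knockouts, 7.62 ± 0.412 at 6 h and 7.31 ± 0.365 at 18 h (SD, n = 3 each). Its differences from untreated knockouts were 0.49 at 6 h (SE 0.252, limma adjusted p = 0.595) and 0.19 at 18 h (limma adjusted p = 0.991). ENSMUSG00000070645 averaged between 4.52 and 4.71 in the 3 knockout groups, below the filter level of 4.79. ENSMUSG00000033826 differed by -0.04 at 6 h (SE 0.351, limma adjusted p = 0.971) and by -0.16 at 18 h (limma adjusted p = 0.999).

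No gene passed in the knockouts. At 6 h limma called 0 genes, with a smallest adjusted p of 0.256. There 1038 genes had an unadjusted p under 0.05, where chance gives 638.8. Groups did not overlap for 9.27% of genes, where chance gives 10%. At 18 h limma called 0 genes, with a smallest adjusted p of 0.119, 657 genes at an unadjusted p under 0.05 where chance gives 638.8, and non-overlapping groups for 16.5% of genes. Between 18 h and 6 h limma called 0 genes, with a smallest adjusted p of 0.176. Here 1141 genes had an unadjusted p under 0.05, again against 638.8 by chance, and groups did not overlap for 13.3%. Single calls appeared when an array was left out: 1 gene at 6 h without replicate 15, 2 at 18 h without untreated replicate 5, and between the times 1 without replicate 13 and 1 without replicate 14. With array weights 22 genes were called at 18 h and 455 between the times.

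The 433 genes called in wild-type mice at 6 h were followed as a set in all groups. Turned to the direction of the call, their mean change from wild-type untreated mice was 0.89 ± 0.0689 (SD, n = 3) in the wild-type 6 h arrays that selected them. For 9 shorter lists of 81 to 319 genes, each called without 1 treated and 1 untreated array, the change measured in those held-out arrays averaged 0.91 (SD 0.211, between 0.54 and 1.18). Over the same 9 lists the knockout change at 6 h averaged 0.069 (between 0.060 and 0.077). The knockout ranges over lists given here show no spread between animals, since every list used the same knockout arrays. In wild-type mice at 18 h the full set of 433 genes was at -0.038 ± 0.0542 (SD, n = 3). In knockouts that full set was at 0.083 ± 0.0243 untreated, 0.15 ± 0.00633 at 6 h and 0.019 ± 0.00889 at 18 h (SD, n = 3 each). The knockout change at 6 h was 0.065 (SE 0.0145), with an exact permutation p of 0.1, the smallest that 3 against 3 arrays allow, and 0.063 without replicate 13. In that contrast 261 of the 433 genes (60.3%) had the wild-type direction. The 25 genes called in wild-type mice at 18 h changed in knockouts by 0.26 (SE 0.0614, exact permutation p = 0.1) at 18 h and by -0.061 (SE 0.0772, exact permutation p = 0.5) at 6 h, against 1.25 (SE 0.0534) in the wild-type arrays that selected them. For 9 lists of 4 to 10 genes called at 18 h without 1 treated and 1 untreated array, the change in the held-out wild-type arrays averaged 1.60 (between 1.20 and 2.11) and that in knockouts at 18 h 0.094 (between -0.23 and 0.27).

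**Figure D3:**
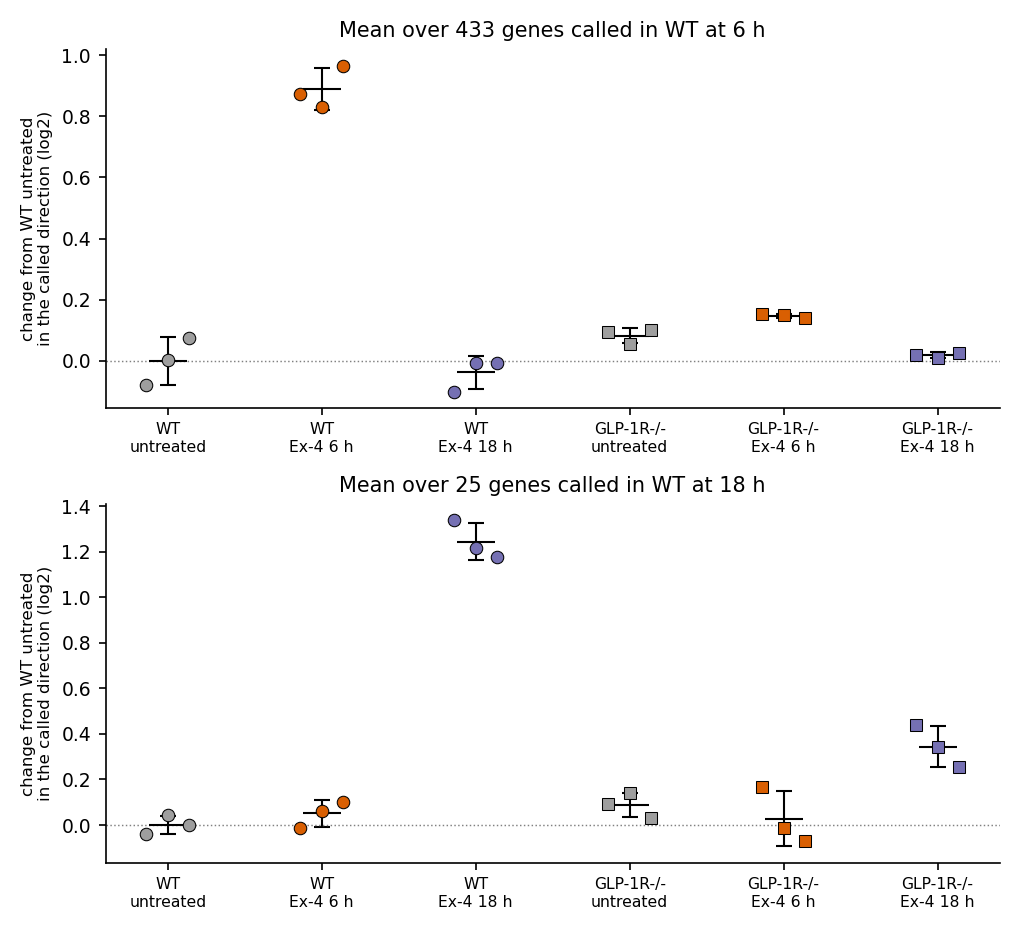
Mean log2 change from wild-type untreated mice, turned to the direction of the call, over the 433 genes called in wild-type mice at 6 h and the 25 called at 18 h, for each array by group (line and error bar, mean and SD of 3 mice). The wild-type arrays at 6 h and 18 h selected these genes, which inflates their own points; the knockout arrays at 6 h average 0.15 in the upper panel, and those at 18 h average 0.34 in the lower.

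Whether the response differed between genotypes was tested with the genotype by treatment contrasts. For ENSMUSG00000024810 the 6 h change was larger in wild-type mice by 3.38 on the log2 scale (SE 0.356, limma adjusted p = 0.000264). For ENSMUSG00000070645 the 18 h change was larger by 4.92 (SE 0.548, limma adjusted p = 0.00107); at 6 h the difference was 2.52 (SE 0.548, limma adjusted p = 0.0619, between 0.0169 and 0.158 over 19 alternatives). For ENSMUSG00000033826 at 6 h it was -2.15 (SE 0.496, limma adjusted p = 0.0732, between 0.019 and 0.27 over 19 alternatives). The 18 h difference of ENSMUSG00000024810 was -1.74 (SE 0.356, limma adjusted p = 0.2, between 0.0445 and 0.566 over 20 alternatives, the lowest with array weights).

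At 6 h 48 genes were called in the interaction, 30 with the more positive change in wild-type mice and 18 with the more negative. Of these, 46 were also called in wild-type mice, whose contrast is part of the interaction, and 0 in knockouts, which had 0 calls in all. The larger fitted change was in wild-type mice for 47. For 37 of the 48 the fitted changes of the genotypes had opposite signs, and the median knockout change, in the direction of the interaction, was -0.13 against a median size of 0.98 in wild-type mice, so that selection on the difference draws on both. At 18 h 3 genes were called, all 3 more positive in wild-type mice, and 2 of them were called in wild-type mice at that time. All 3 had fitted changes of opposite sign in the genotypes, 2 of them larger in wild-type mice and 1 larger in knockouts. At an unadjusted p under 0.05 there were 1313 genes at 6 h and 601 at 18 h, where chance gives 638.8. The 6 h count was 18 without wild-type untreated replicate 1, 29 without wild-type untreated replicate 2, 30 without wild-type 6 h replicate 7, 27 without wild-type 6 h replicate 9, 17 without knockout untreated replicate 4 and 109 without knockout 6 h replicate 13. It was 12 in a fit to only the groups compared and 284 with array weights. The 18 h count was 1 without knockout 18 h replicate 17, 1 without knockout 18 h replicate 18 and 1 without knockout untreated replicate 6, and it was 19 with array weights and 6 when array 13 was left out of the shared spread.

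**Figure D4:**
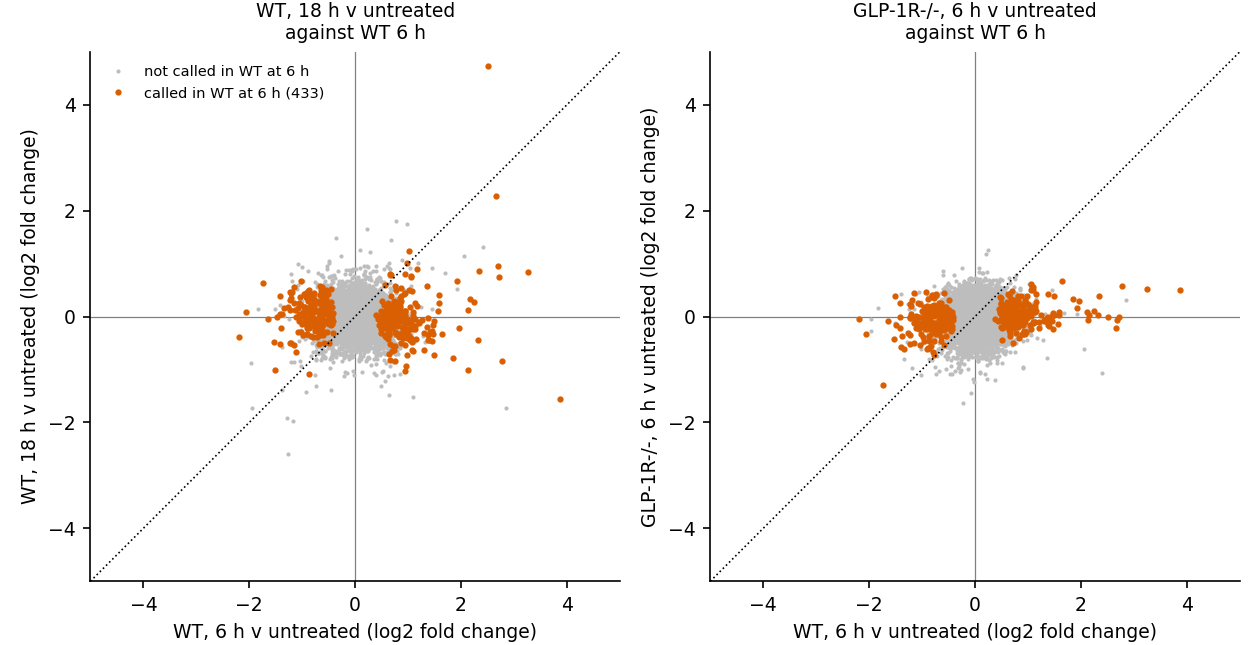
Log2 fold change of each of the 12775 tested genes in wild-type mice at 6 h (horizontal axis) against wild-type mice at 18 h (left) and GLP-1R-/- mice at 6 h (right), each from the untreated mice of its genotype. Orange points are the 433 genes called in wild-type mice at 6 h, and the dotted line marks equal changes. In the right panel 261 of the 433 share the wild-type direction.

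Across the 12775 genes, the wild-type and knockout changes, which share no arrays, correlated with a Pearson r of 0.0838 at 6 h (0.122 without replicate 13), 0.168 at 18 h, and 0.158 between 18 h and 6 h (0.314 without replicate 13). Spearman's rho was 0.0657 (0.14 without replicate 13), 0.2, and 0.129 (0.339 without replicate 13). These are correlations across genes, which are not independent replicates, for 3 pairs of contrasts.

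Untreated GLP-1R-/- mice were compared with untreated wild-type mice to find differences present before any treatment. ENSMUSG00000024810 was lower in knockouts by -1.60 on the log2 scale (SE 0.252, limma adjusted p = 0.00677). ENSMUSG00000033826 was lower by -2.19 (SE 0.351, limma adjusted p = 0.00677), at 7.99 ± 0.416 in knockouts against 10.2 ± 0.773 in wild-type mice (SD, n = 3 each). In a limma fit to only the groups compared its difference was also -2.19 (SE 0.361), with an adjusted p of 0.0527. ENSMUSG00000070645 differed by -0.38 (SE 0.387, limma adjusted p = 0.999). In all, 79 genes were called, 32 higher and 47 lower in knockouts, of which 19 and 27 differed at least 2-fold. The largest differences were 4.09 and -4.60 on the log2 scale. As a set, turned to the direction of the call, these 79 genes were at 1.31 ± 0.0187 in untreated knockouts, 1.19 ± 0.0257 at 6 h and 1.03 ± 0.0625 at 18 h, against 0.16 ± 0.0399 and 0.092 ± 0.0909 in wild-type mice at 6 h and 18 h (SD, n = 3 each). In both treated knockout groups 76 of the 79 lay on the same side of the wild-type untreated mean. At an unadjusted p under 0.05 there were 962 genes against 638.8 by chance, and 13.4% of tested genes had groups that did not overlap, where chance gives 10%. The count was 40 without wild-type untreated replicate 1, 40 without wild-type untreated replicate 2, 41 without knockout replicate 4 and 31 without knockout replicate 5. It was 177 with array weights and 137 when array 13 was left out of the shared spread.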

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

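The tests of precision lost through knockout 6 h array 13 or unequal arrays, of a hidden knockout response and of a time difference without the receptor were chosen after the results were seen. The genotype by time contrast was added after the data were examined, and the bound on its splits was set after its count was seen and before the splits were drawn. The responses of the genotypes were called as different, by the interaction itself, for 48 genes at 6 h and 3 at 18 h. They differed for ENSMUSG00000024810 at 6 h, by 3.38 on the log2 scale (SE 0.356, limma adjusted p = 0.000264, between 4.04e-06 and 0.00432 over 19 alternatives), and for ENSMUSG00000070645 at 18 h, by 4.92 (SE 0.548, limma adjusted p = 0.00107, between 0.000262 and 0.0066 over 20 alternatives). For both, all 3 treated wild-type arrays lay above all 3 untreated ones, but the rule for naming genes required this, so it adds no support.

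Other splits of the same arrays, within each genotype, cannot decide on chance for these counts, because some of them keep the wild-type change. At 6 h 9 of 100 splits called as many genes, the real one included, with a real count of 48 and 169 as the highest other. At 18 h 5 of 100 did, with 3 real and 22 as the highest other. The splits that reached the real count at 6 h kept the wild-type change. All 8 drawn splits that left the wild-type arrays in their groups called at least 48 genes, and the splits that parted them called at most 1. The real split keeps these arrays too, so this does not explain why some splits called several times the real count. The cause of that was not tested. At 18 h 4 of the 7 splits that left the wild-type arrays in place called as many, and those that parted them called at most 2. A split that moves only knockout arrays keeps the wild-type change, so this share has little room to fall under 0.05 when the change lies in 1 genotype.

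No gene passed in the knockouts at either time with limma, against 433 in wild-type mice at 6 h. Knockout genes at an unadjusted p under 0.05 numbered 1038 at 6 h and 657 at 18 h, where chance gives 638.8. Loss of precision through array 13 is argued against at 6 h for a response of wild-type size. Without that array limma still called 0 genes, and with array weights 0. The first of these fits had fewer arrays in the group, but the wild-type 6 h count stayed at 176 or more when single arrays were left out. At 18 h unequal precision stays open, since leaving array 13 out of the shared spread gave 0 calls and array weights, which weight every array, gave 22 (and 455 between the times). A response of wild-type size hidden by the small groups is argued against at 6 h, since the 433 genes changed in knockouts by 0.0652 (SE 0.0145), and over the 9 lists of 81 to 319 genes the held-out wild-type change averaged 0.906 and the knockout change 0.0688. It is argued against at 18 h on fewer genes: the 25 genes changed in knockouts by 0.256 (SE 0.0614), 20 of them in the wild-type direction, and over lists of 4 to 10 genes the held-out wild-type change averaged 1.60 and the knockout change 0.094. The splits cannot decide whether a response needs the receptor. Of 100 splits 9 reached the interaction count, and the bound set on that share beforehand was wrong, because the 8 others that reached it all kept the wild-type change. The interaction itself called 48 genes at 6 h, 46 of them also called in wild-type mice and 0 in knockouts. These overlaps add no support, since the interaction contains the wild-type contrast and no gene was called in knockouts. These 48 genes were called as differing in response with the genotype, and their count ran from 12 to 284 over the alternatives. For the other genes the question stays open. A smaller knockout change is not excluded at either time.

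More genes differed between 18 h and 6 h in wild-type mice than between either time and untreated mice, 1389 against 433 and 25. For 1244 of the 1389 (89.6%) the fitted changes from untreated mice had opposite signs at the 2 times, which selection on their difference favours. A single array that decides this is argued against, since leaving out 1 of the 6 arrays left at least 810 calls, the lowest without 6 h replicate 9, with 842 without 18 h replicate 10 and 874 without 6 h replicate 7. A difference between collection times that does not need the receptor may be part of it but not the whole, since the 1389 genes moved in knockouts by a median of 0.117 and a mean of 0.127 (SE 0.026). In knockouts 974 of them (70.1%) had the wild-type direction. Without array 13 the mean knockout change of the 1389 genes was 0.15 (SE 0.0152). Over 9 lists of 497 to 974 genes called without 1 array of each time, the held-out wild-type change averaged 0.859 and the knockout change 0.143. The genotype by time contrast called 197 genes (84 higher and 113 lower, or 53 and 125 with median centring). These genes were called as differing in time course between the genotypes, ENSMUSG00000024810 by -5.12 (SE 0.356, limma adjusted p = 9.73e-07). The splits cannot decide on chance for this count. It was reached by 10 of 100 splits and the highest other called 1002, but the 9 others that reached it all kept the wild-type groups. The bound set on that share was thus wrong here too. The 197 became 96, 92 and 87 without knockout 18 h replicates 16, 17 and 18, 124 and 99 without wild-type 18 h replicates 10 and 11, 112 and 97 without wild-type 6 h replicates 7 and 9, and 284 without knockout 6 h replicate 13. They became 1512 with array weights, 408 at a threshold of 0.1 and 108 in a fit to only the groups compared.

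For the contrasts of 3 against 3 arrays there are 10 splits, too few for a share under 0.05. The real counts and the highest of the other splits were 433 and 0 for wild-type mice at 6 h, 25 and 1 at 18 h, 1389 and 1 between the times, and 79 and 0 for knockout against wild-type untreated mice, where in each 1 split, the real one, reached the real count. For the knockouts they were 0 and 0 at 6 h, 0 and 1 at 18 h and 0 and 0 between the times, where all 10 splits reached the real count of 0 with limma.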

How the results depend on the processing

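No paired analysis was possible because the array numbers in the titles are unique across the groups. Without a filter, with a filter at the 50th percentile, with quantile normalisation, with median centring and with eBayes trend and robust, each count of calls and the overlap stayed within 1.5 times its value. Array weights gave 1243 calls in wild-type mice at 6 h, 212 at 18 h and 3423 between the times, 22 in knockouts at 18 h and 455 between the times, 284 and 19 in the interactions at 6 h and 18 h, 177 for knockout against wild-type untreated mice, and an overlap of 23. A threshold of 0.1 gave 683, 49 and, in the 6 h interaction, 113. A minimum change of 1 on the log2 scale gave 105, 12, 319 between the times and 46 for untreated mice, by its construction fewer. A fit to only the groups compared gave 4 at 18 h and 12 in the 6 h interaction, with fewer arrays to estimate the spread. Leaving array 13 out of the shared spread, chosen after seeing the data, gave 880, 86, 2419, 6 in the 18 h interaction, 137 for untreated mice and an overlap of 12, and 0 in knockouts at 18 h with limma (657 at an unadjusted p under 0.05 in the fit with all arrays). Apart from these constructions, the cause was not tested.

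With each array left out in turn the counts ran from 176 to 378 in wild-type mice at 6 h, 8 to 17 at 18 h and 810 to 1163 between the times; 0 to 1, 0 to 2 and 0 to 1 in knockouts; 17 to 109 and 1 to 4 in the interactions; 31 to 60 for untreated mice; and 2 to 7 for the overlap. A group left with 2 arrays had its spread estimated from all groups. Of 179 values of the 3 named genes past the threshold, 173 stayed past it and 6 did not, all in the same direction, and of 187 that had not passed, 9 came to pass in the same direction. Reversals were among differences that did not pass: ENSMUSG00000070645 in knockouts at 6 h (0.00039) was -0.12 with quantile normalisation, -0.054 with median centring, -0.064 with array weights and -0.26 to 0.31 with arrays left out; ENSMUSG00000033826 in the 18 h interaction (-0.23) was 0.13 with array weights and -0.67 to 0.070 with arrays left out, and in knockouts -0.27 to 0.14 at 6 h and -0.39 to 0.016 at 18 h. The causes of these reversals were not tested. The mean of several probe sets, a test of all probe sets and the gene list tests were not run, as the table has 1 row per gene and no symbols. RMA gives no background level, so what dim signals hide is unknown.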

Other observations

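The tests of array 13 and the split of the untreated arrays were chosen after the values were seen. Genes called between 18 h and 6 h in wild-type mice differed in brightness by direction: at 6 h, 134 of the 773 genes that were lower at 18 h (17.3%) lay among the brightest 10% of tested genes, against 26 of the 616 that were higher (4.22%). Of the higher ones 58 lay below the filter level of 4.79 at 6 h. Both shares move with regression from a high or low starting level, so they describe these lists and no more.

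Differences between the genotypes before treatment overlapped with the wild-type response: 19 genes were called both between untreated knockout and wild-type mice and in wild-type mice at 6 h, where independent lists would share 2.68. Of these, 14 had the same direction and 5 the opposite one. ENSMUSG00000033826 was among the 14, at 7.99 in wild-type mice at 6 h and 7.99 in untreated knockouts, and ENSMUSG00000024810 among the 5. Both contrasts use the same 3 wild-type untreated arrays, whose chance values push such genes in the same direction, and with these arrays split 2 and 1 between the contrasts, in 6 ways, limma calls shared the same direction for 0 to 4 genes (mean 2, where independent lists would share 0.0587 to 0.406) and the opposite one for 0 to 4 (mean 2.33). The excess of the same direction was thus not seen without shared controls, in lists that were shorter, with 26 to 378 and 6 to 60 calls.

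The 79 genes that separated untreated knockouts from wild-type mice moved toward the wild-type level in treated knockouts, by -0.12 at 6 h (SE 0.0184) and -0.28 at 18 h (SE 0.0377), each with an exact permutation p of 0.1, the smallest possible. They were chosen in the untreated knockout arrays, and a return toward the mean in arrays that did not choose them has the same sign. Such a return does not cover the step between knockouts at 6 h and 18 h, since neither group chose the genes. That step was -0.16 (SE 0.039, exact permutation p = 0.1), and its cause was not tested.

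Knockout 6 h array 13 stood apart from the other 17, with correlations of at most 0.966 with any array where all other pairs reached at least 0.970. A compressed signal range may account for it: across genes, its difference from its group mates fell with the mean level, with a Spearman rho of -0.455, where the other 17 arrays lay between -0.266 and 0.302, and its median deviation went from 0.40 in the dimmest 20% of genes to -0.40 in the brightest 20%. A swap with or a wrong label among the 3 wild-type groups is argued against: over the 79 genes that separated untreated knockouts from wild-type mice, array 13 scored 1.162, where the wild-type arrays reached at most 0.204 and the other knockout arrays at least 0.967. A swap with or a wrong label among the other 2 knockout groups stays open, since limma called 0 genes between the knockout groups (657 to 1141 at an unadjusted p under 0.05) and the highest mean correlation with one of them, 0.959, is low as those of this array are with every group. A response of that animal of its own stays open, since 1136 genes lay more than 2-fold outside both group mates, 333 above and 803 below, and no second array measured the animal. An outside sample was not tested.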
